A study of Mus musculus with 6 samples.

How the data were processed

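Poly(A) RNA from mouse liver was sequenced in 6 libraries, 3 from male mice of genotype IRE1fl and 3 of genotype IRE1PKO, all on a diet labelled HFD, read here as high-fat diet. Livers were taken after 16 hours of fasting and 4 hours of feeding, per the labels. The authors deposited 1 table of raw counts per gene symbol with a column for each library, and replicates were not pooled. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program and the annotation are not given in the sources used here. The values were whole numbers that summed to between 35776219 and 39277435 per library. Among values from 1 to 8, even values outnumbered odd ones by 2.58 to 3.19 times, the pattern that appears when both mates of a read pair are counted. Which of reads or fragments the deposited counts hold is not stated, so floors based on counts cover counting error only and may be too low. The table held 27 date-like names of the kind a spreadsheet makes from gene symbols, with 0.178% of all counts. They stayed in the library totals and the tests, and none is named.

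Each column was matched to a sample by genotype and replicate number in its name. Of 35976 genes in the table, 22427 had a count in at least 1 library and 14954 passed edgeR's filter on low counts (filterByExpr, default settings). Counts were scaled by the trimmed mean of M-values (TMM) and tested with edgeR 4.0.16 (R 4.3.3), using the quasi-likelihood test with a robust dispersion trend, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. CPM values are counts relative to the TMM-scaled library totals. Log2 fold changes are IRE1PKO over IRE1fl and are given with their standard error (SE). An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, so single genes were tested only in the model fitted over all genes. The labels do not say that the libraries come from separate animals, so the p-values measure the spread between these libraries, which may be technical. Pairs of libraries of the same group differed by a chi-square of 30.9 to 69.2 per gene, and none was a copy of another.

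Before the data were examined, 40 gene lists of pathways, hormone responses and cell types were fixed, of which 38 had 5 or more tested members. Of the 931 symbols in them, 8 were looked up as older names through a RefSeq gene table of the GRCm38.p6 assembly, the same build as mm10, and 10 were not found. Coordinates come from that table. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 38 lists. Camera compares a list with all other genes. The same test with a correlation estimated from each list, and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were run as alternatives. With the estimated correlation, camera also takes its p from the residual degrees of freedom of the libraries, not from the number of genes. No list was called in that setting, and the lowest adjusted p was 0.277. Fry called 16 lists, 14 of them also called by camera. Member counts are given with adjustment over all genes and adjusted over the list alone.

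Genes were named by a rule also set before the data were examined. It takes Ern1 and Xbp1, then the 8 largest and the 8 smallest log2 fold changes among genes past the threshold whose groups did not overlap and whose mean was 1 CPM or more, without predicted models and pseudogenes. It adds up to 4 members with the smallest p from each list called by camera, and 1 from each other list where a member passed. This gave 94 genes. Some of them are not reported here. Other genes named in the text were chosen after their values were seen, and are said to be so.

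The steps were tested on counts simulated for the 14954 tested genes from the means, library sizes and dispersions of this comparison, with 200 genes changed. The test recovered 26.9% of 67 genes changed 1.5-fold, 73.1% of 67 changed 2-fold and 90.9% of 66 changed 4-fold, and 8.63% of its 139 calls were false. With no gene changed, no gene and no list was called. With the circadian list shifted by a log2 value of 0.5, that list alone was called. Fewer genes were changed than the 1426 called in the data, so the shares recovered there may differ. The simulated genes varied independently, so the simulation does not check the lists against genes that vary together.

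Alternatives set before the data were examined were DESeq2 size factors, library totals as the only scaling, no filter on low counts, a filter at a mean of 1 CPM, the DESeq2 1.42.0 Wald test, limma-voom, a threshold of 0.1, a dispersion trend without robust fitting, the replicate number as a block, and each library left out in turn. Halved counts were added after the data were seen. So were the male-biased list without Mup and Cyp4a12 genes and the female-biased list without Cyp2b, Cyp3a and Sult genes. All 10 splits of the 6 libraries into 3 and 3 were refitted. Each of the 9 other splits sets 2 libraries of a genotype and 1 of the other against the reverse. They keep part of the difference between the genotypes, which also widens the spread within their groups. Gene and list calls in them therefore do not measure false calls. Since no list was called with the estimated correlation, lists are described by their members first.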

Results

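Bulk RNA sequencing of mouse liver was used to compare the genotypes IRE1PKO and IRE1fl under a high-fat diet, with 3 libraries of each. IRE1, encoded by Ern1, is a sensor of the unfolded protein response in the endoplasmic reticulum. The labels do not spell out PKO, and the series title places the study in the communication between pituitary and liver in fatty liver disease. Total counts ranged from 35776219 to 39277435 per library, and 18649 to 19153 genes had at least 1 count. Mitochondrial genes took 3.84% to 4.98% of counts and Alb, the albumin gene, 5.56% to 7.19%. Log2 CPM correlated across genes with r of 0.981 to 0.987 within a group and 0.958 to 0.974 between groups, although genes are not independent replicates. The first principal component held 52.0% of the variance and separated the genotypes.

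Liver Ern1 (chromosome 11, 106397620 to 106487796) had 61.2, 49.3 and 60.8 CPM in the IRE1fl libraries and 45.7, 36.6 and 44.2 CPM in the IRE1PKO libraries. It fell by 0.44 on the log2 scale (SE 0.11), with an adjusted p of 0.0357 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. If the deletion lies outside the liver, this value checks no label. The Ern1 call rested on nearly all libraries: it was lost without any single library other than IRE1fl 02, with an adjusted p of up to 0.137, and also with library totals as the only scaling and with limma-voom. Xbp1, whose transcript IRE1 splices, had 290.0 ± 72.7 CPM in IRE1fl and 205 ± 52.2 CPM in IRE1PKO (SD, n = 3 each), a log2 fold change of -0.50 (SE 0.24) that did not pass (edgeR adjusted p = 0.259). With each library left out in turn, the Xbp1 value ran from -0.70 to -0.29 and never passed. It was -0.29 without IRE1fl 03 and -0.33 without IRE1PKO 02. Of 31 tested genes of the list of XBP1s targets and ER-associated degradation, 2 rose over all genes and 1 adjusted over the list alone. Dnajb9, an ER co-chaperone, rose by a log2 value of 0.48 (SE 0.09). None of 18 ER chaperones and ATF6 targets passed, over all genes or adjusted over the list alone. The list medians were -0.10 and -0.05, and camera called neither list (adjusted p = 0.166 and 0.379). With each library left out in turn the XBP1s median ran from -0.14 to -0.05, and that list was called without IRE1PKO 01 (camera adjusted p = 0.0482). The ER chaperone median ran from -0.17 to 0.02, never called.

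In IRE1PKO livers, 15 of 30 fat synthesis genes, 12 of 24 lipid droplet genes, 13 of 26 collagen and stellate cell genes and 5 of 16 recruited macrophage genes rose. Of male-biased genes 13 of 29 fell, and of amino acid metabolism genes 16 of 27. Camera called each of these lists, and none with an estimated correlation (adjusted p = 0.277 for each). In all, 849 genes were higher and 577 lower in IRE1PKO among 14954 tested, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 317 were at least 2-fold higher and 184 at least 2-fold lower. The groups did not overlap for the 1426 called genes; among all tested genes 31.0% had groups that did not overlap, where chance gives 10%. With library totals as the only scaling, 1148 were higher and 415 lower, so the higher share of calls was 73.4% in place of 59.5%. The counts depended on single libraries. They were 553 higher and 343 lower without IRE1fl 02, 472 and 317 without IRE1fl 03, 398 and 255 without IRE1PKO 01, and 484 and 331 without IRE1PKO 02.

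**Figure D1:**
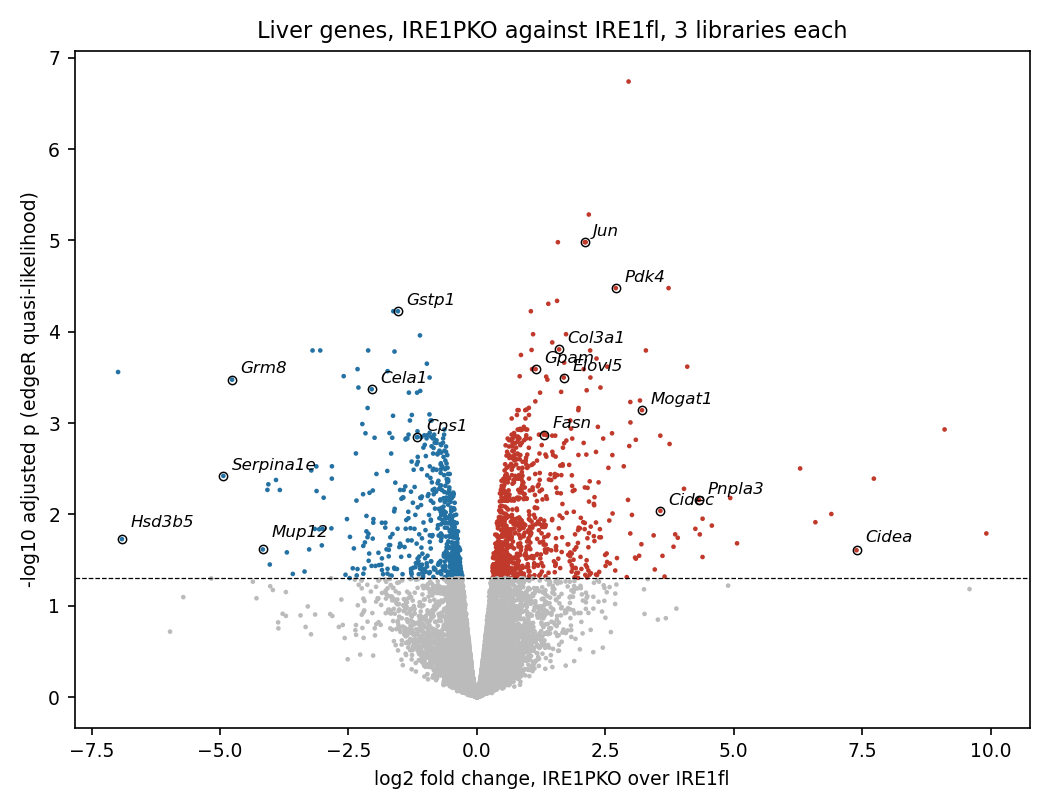
Each point is 1 of the 14954 tested genes, with the log2 fold change of IRE1PKO over IRE1fl on the horizontal axis and -log10 of the edgeR adjusted p on the vertical axis, over 3 libraries per group. Red points are the 849 genes higher and blue points the 577 genes lower in IRE1PKO, the dashed line marks an adjusted p of 0.05, and open circles mark named genes.

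The largest rises were in genes that were nearly silent in IRE1fl. Sprr1a, a cornified envelope gene, had no counts in the IRE1fl libraries and 3.22 ± 2.43 CPM in IRE1PKO (5.98, 2.28 and 1.39 in its libraries). Its IRE1PKO mean was 38.8 times a floor of 3 counts per library, which covers counting error only and may be too low. Cidea, a lipid droplet protein (chromosome 18, 67343564 to 67367794), rose from 0.113 ± 0.150 to 19.1 ± 12.2 CPM (SD, n = 3). Pnpla3, a lipid droplet acylhydrolase (chromosome 15, 84167776 to 84189521), rose from 0.778 ± 0.207 to 15.6 ± 9.46 CPM. Ly6d, A4gnt, Gprc5b, Pls1 and Ephb2 rose by log2 values of 4.57, 4.39, 4.39, 4.09 and 4.03. Hsd3b5, a male-biased steroid dehydrogenase (chromosome 3, 98618636 to 98645534), fell from 193 ± 79.2 to 1.58 ± 1.53 CPM, a log2 fold change of -6.91 (SE 0.87). Serpina1e, an alpha-1-antitrypsin gene (chromosome 12, 103946931 to 103956897), fell from 5299.6 ± 2787 to 173 ± 26.4 CPM. Grm8, Mup12, Adgrf1, Mup16, Mup19 and Ces4a had log2 fold changes of -4.77, -4.17, -4.03, -3.58, -3.35 and -3.16. The Mup and Serpina1 genes are families of near-identical copies, so the assignment of reads among members is uncertain. The Cidea call was lost without IRE1PKO 01 or any one IRE1fl library (edgeR adjusted p up to 0.101), and the Hsd3b5 call without IRE1fl 02, IRE1fl 03, IRE1PKO 01 or IRE1PKO 02 (up to 0.0833). Of these 16 genes, Pnpla3, Pls1, Ephb2, Serpina1e and Grm8 passed without each library in turn, and each other gene lost its call without at least 1. Without the filter on low counts the calls of Sprr1a, Gprc5b, Adgrf1, Mup16 and Mup19 were lost (edgeR adjusted p of 0.0517, 0.0547, 0.103, 0.0551 and 0.0558), and with limma-voom that of Cidea (adjusted p = 0.0801). Of the 93 named genes that passed, 60 did so without each library in turn.

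**Figure D2:**
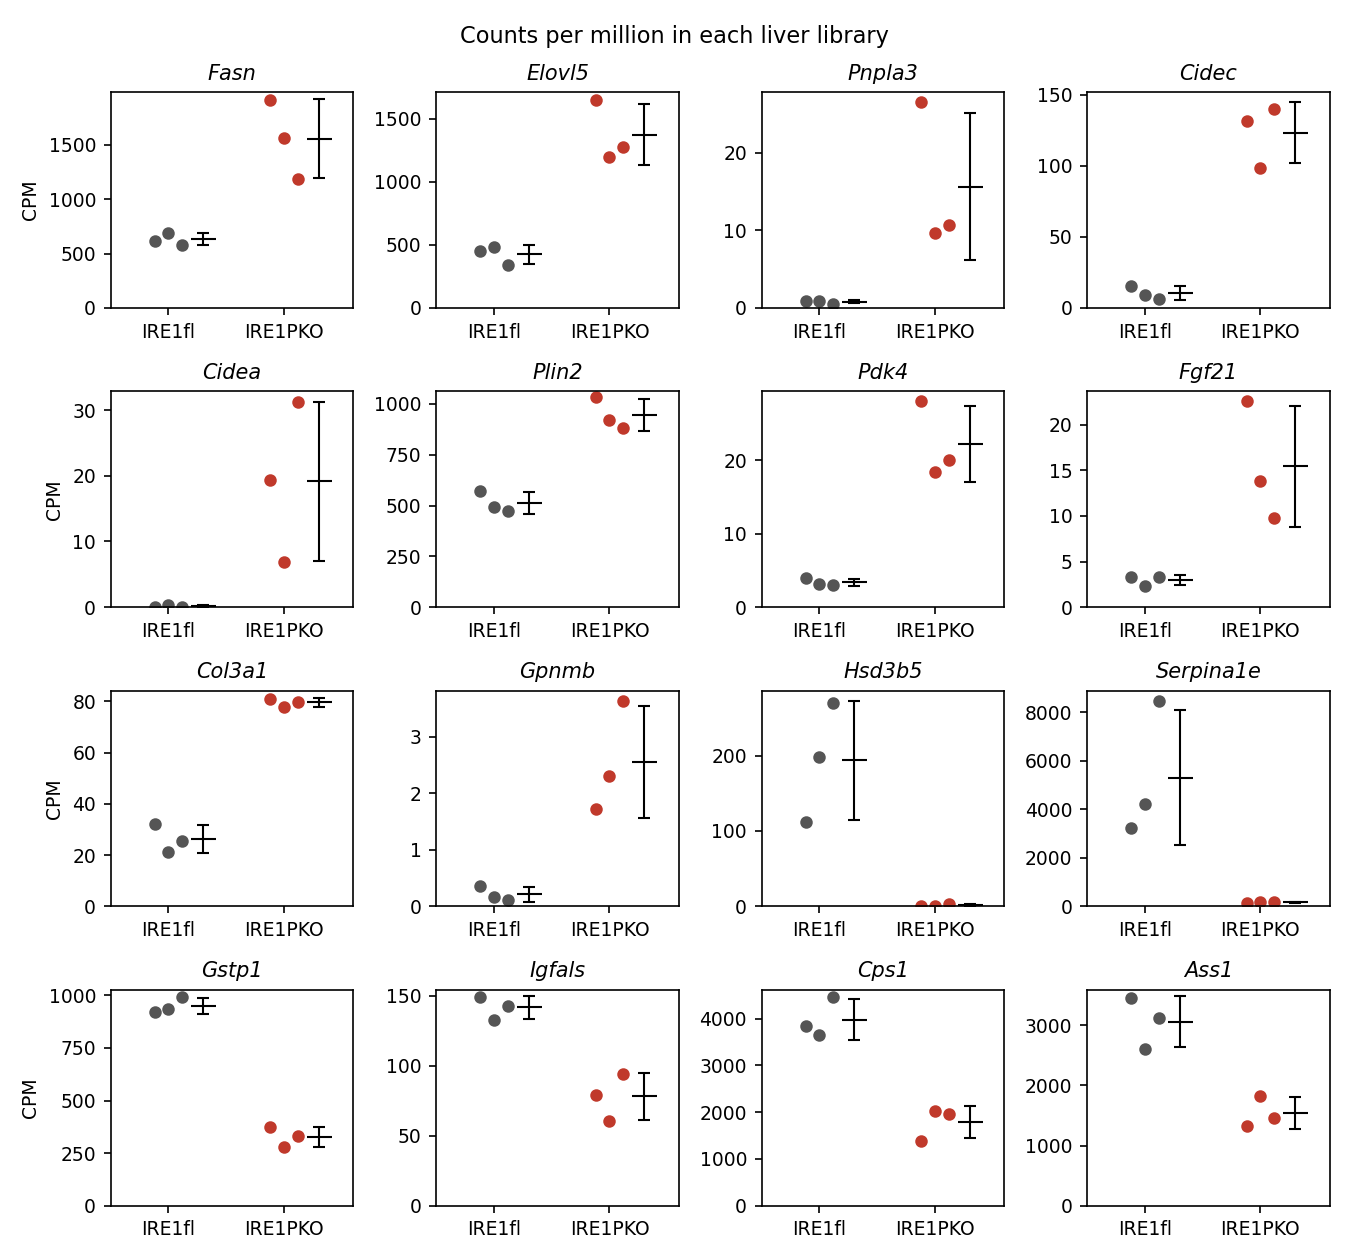
CPM of 16 named genes in each liver library, with a linear axis from 0 for each gene; points are libraries, and the horizontal mark with bars is the mean ± SD of 3 libraries. For every gene shown, the 3 IRE1PKO libraries lie wholly above or wholly below the 3 IRE1fl libraries.

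Of 30 tested fat synthesis genes, targets of SREBP1c and ChREBP, 15 rose and none fell over all genes, while 18 rose and 3 fell adjusted over the list alone, with a median log2 fold change of 0.70 (camera adjusted p = 7.5e-07). The adjusted p was 0.277 with an estimated correlation. Fasn, the fatty acid synthase, rose from 631 ± 55.8 to 1556 ± 363 CPM, a log2 fold change of 1.30 (SE 0.16). Elovl5, a fatty acid elongase, rose by 1.69 (SE 0.16), Gpam, the acyltransferase that starts glycerolipid synthesis, by 1.14 (SE 0.11), and Acaca, an acetyl-CoA carboxylase, by 0.95 (SE 0.12). Of 24 genes of lipid droplets and fatty acid uptake, 12 rose and none fell over all genes, and 16 rose and 1 fell adjusted over the list alone. Their median was 0.67 (camera adjusted p = 7.5e-07; adjusted p = 0.277 with an estimated correlation). Cidec, a droplet fusion protein, rose from 10.4 ± 4.82 to 123 ± 21.6 CPM. Mogat1, a monoacylglycerol acyltransferase, rose by 3.21 (SE 0.33), Pparg by 1.85 (SE 0.25) and the droplet coat gene Plin2 by 0.88 (SE 0.11).

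Cholesterol synthesis genes had a median of 1.12 over 25 tested members, but only 3 rose over all genes and 3 adjusted over the list alone. Sc5d, a sterol desaturase, rose by 0.94 (SE 0.18), a call that was lost without IRE1fl 03 (edgeR adjusted p = 0.0749) or IRE1PKO 02. Camera called the list (adjusted p = 2.8e-07), with an adjusted p of 0.439 with an estimated correlation and 0.124 by fry. Of 33 genes of fatty acid oxidation and ketogenesis, 11 rose and none fell over all genes, and 18 rose and 1 fell adjusted over the list alone. The median was 0.33 (camera adjusted p = 7.0e-06; adjusted p = 0.407 with an estimated correlation). Pdk4, a kinase that restrains pyruvate oxidation, rose by 2.70 (SE 0.19), the hormone gene Fgf21 by 2.37 (SE 0.32), Acot2 by 1.90 (SE 0.26) and Pex11a by 1.10 (SE 0.16). Lipoprotein assembly and secretion had 2 members higher and 2 lower of 23, and 3 and 4 adjusted over the list alone, and was not called (camera adjusted p = 0.871).

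Male-biased liver genes had the lowest median of the tested lists. Of 29 tested members, 13 fell and 1 rose over all genes, and 25 fell and 2 rose adjusted over the list alone, with a median of -1.71 (camera adjusted p = 9.2e-14; adjusted p = 0.277 with an estimated correlation). Gstp1, a glutathione transferase, fell from 949 ± 36.7 to 327 ± 47.6 CPM. Cspg5 had a log2 fold change of -2.82 (SE 0.44) and the complement gene C8a of -1.04 (SE 0.19), though the C8a call was lost without IRE1PKO 01 (edgeR adjusted p = 0.0646). The member that rose was Cyp4a12a, by 2.18 (SE 0.33). It has a near-identical copy, Cyp4a12b, which fell by 2.42 (SE 0.46); both were named after their values were seen, and the split of reads between them is uncertain. Of 22 female-biased genes, 6 rose and none fell over all genes, and 8 rose and none fell adjusted over the list alone. Their median was 1.20 (camera adjusted p = 1.4e-06; adjusted p = 0.277 with an estimated correlation), and 0.73 without the filter on low counts. Rtn4, a reticulon of the ER membrane, rose by 0.97 (SE 0.11) and Fmo2, a flavin monooxygenase, by 0.72 (SE 0.13).

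Of 27 tested genes of amino acid and one-carbon metabolism, 16 fell and none rose over all genes, and 20 fell adjusted over the list alone, with a median of -0.64 (camera adjusted p = 3.9e-10; adjusted p = 0.277 with an estimated correlation). The urea cycle gene Ass1 fell from 3056 ± 424 to 1535 ± 265 CPM, Asl had a log2 fold change of -0.83 (SE 0.11), Got1 of -0.84 (SE 0.12) and Bcat2 of -0.60 (SE 0.09). Of 19 periportal hepatocyte markers, 11 fell and 1 rose over all genes, and 13 fell and 2 rose adjusted over the list alone. Their median was -0.60 (camera adjusted p = 7.0e-06; adjusted p = 0.277 with an estimated correlation). Cps1, which starts the urea cycle, fell from 3983 ± 429 to 1787 ± 349 CPM and Cyp2f2 by 1.02 (SE 0.14). Ass1, Asl, Gls2 and Sds are in both lists, the latter pair named after their values were seen. Of 20 hepatocyte identity genes, 6 fell over all genes and 9 adjusted over the list alone, with a median of -0.22 (camera adjusted p = 1.9e-04; adjusted p = 0.277 with an estimated correlation). Serpina1a fell by 0.90 (SE 0.11) and Fah by 0.49 (SE 0.10). Cps1 and Arg1, which both fell, are in the identity and the periportal list, as is Alb, so these lists are not separate evidence. Of 17 pericentral markers, 1 fell over all genes and none passed adjusted over the list alone. The pericentral list was not called (median -0.15, camera adjusted p = 0.168), but it was without IRE1fl 01 (median -0.25) or IRE1PKO 02 (median -0.27), with an adjusted p down to 0.0217. With each library left out in turn, the periportal median ran from -0.66 to -0.52 and the pericentral median from -0.27 to -0.06. The pericentral call against all other genes therefore turned on single libraries. A contrast between the periportal and pericentral lists was not tested.

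**Figure D3:**
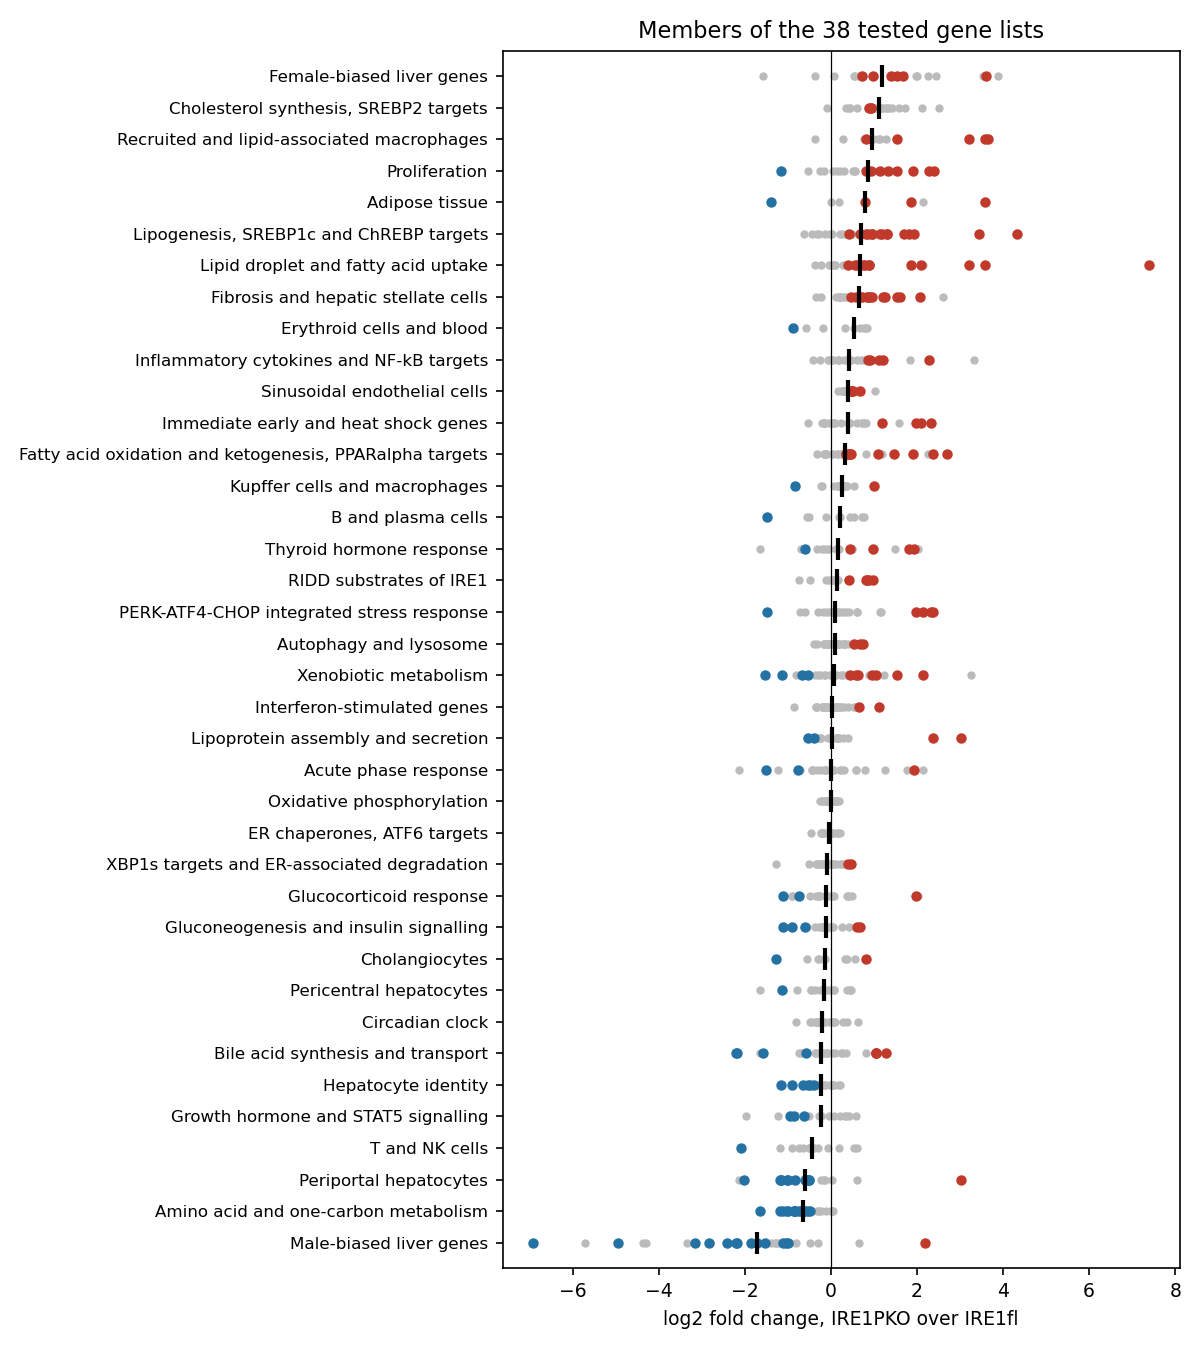
Log2 fold change (IRE1PKO over IRE1fl, horizontal axis) of each tested member of the 38 tested lists, ordered by the list median, which is the black mark. Red and blue points are members higher or lower in IRE1PKO at an edgeR adjusted p under 0.05 over all genes, and grey points did not pass; male-biased genes have the lowest median, -1.71, and female-biased genes the highest, 1.20.

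Of 26 tested collagen and stellate cell genes, 13 rose and none fell over all genes, and 16 rose adjusted over the list alone, with a median of 0.66 (camera adjusted p = 2.8e-09; adjusted p = 0.277 with an estimated correlation). Col3a1 rose from 26.2 ± 5.45 to 79.6 ± 1.61 CPM, Col1a2 by 1.53 (SE 0.17), Col4a1 by 1.21 (SE 0.14) and the stellate cell gene Lrat by 0.96 (SE 0.13). Of 16 markers of recruited and lipid-associated macrophages, 5 rose over all genes and 10 adjusted over the list alone. Their median was 0.96 (camera adjusted p = 6.2e-06; adjusted p = 0.277 with an estimated correlation). Gpnmb rose from 0.213 ± 0.131 to 2.56 ± 0.985 CPM, Cd63 by 1.53 (SE 0.23) and Spp1, which cholangiocytes also express, by 0.81 (SE 0.13). Of 19 Kupffer cell and macrophage genes, 1 rose and 1 fell, with the same counts adjusted over the list alone, and camera did not call the list (adjusted p = 0.0556). It was called without IRE1fl 01 or IRE1PKO 03 (camera adjusted p down to 0.00815), and its median ran from 0.13 to 0.38 with each library left out in turn. Marco, a scavenger receptor, fell by 0.84 (SE 0.13).

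Of 19 sinusoidal endothelial markers, 5 rose over all genes and 11 adjusted over the list alone, with a median of 0.40. Camera called the list (adjusted p = 1.5e-05), with an adjusted p of 0.439 with an estimated correlation and 0.0963 by fry. Without IRE1PKO 02 the endothelial median was 0.25. Flt4 rose by 0.68 (SE 0.14), a call lost without IRE1fl 03 or IRE1PKO 01 (edgeR adjusted p up to 0.0619). Of 15 T and NK cell genes, Cd4 alone passed over all genes, and 1 adjusted over the list alone. Cd4 had a log2 fold change of -2.09 (SE 0.37), and the list median was -0.45 (camera adjusted p = 0.0357; adjusted p = 0.39 with an estimated correlation, 0.122 by fry). The T and NK call was lost without IRE1fl 01 (median -0.20, camera adjusted p = 0.207) or IRE1PKO 01 (median -0.35, 0.175). Of 10 B and plasma cell genes 1 fell, Jchain with a log2 fold change of -1.48 (SE 0.33), a call lost without IRE1fl 03, IRE1PKO 01 or IRE1PKO 02 (edgeR adjusted p up to 0.0894). The same number fell adjusted over the list alone, and the list was not called (camera adjusted p = 0.873). Of 10 cholangiocyte genes, 1 rose and 1 fell by either adjustment (camera adjusted p = 0.937). Of 9 erythroid genes, Alas2 fell by 0.88 (SE 0.12) and no other passed by either adjustment (camera adjusted p = 0.792). Only 4 neutrophil genes and 1 pancreatic acinar gene were tested, too few for camera. No neutrophil gene passed by either adjustment. Cela1, of the acinar list, fell by 2.05 (SE 0.18), past the test by both. It was the only 1 of 14 listed acinar genes past the filter on low counts, so its fall does not speak for acinar tissue.

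Of 26 inflammatory and NF-kB genes, 5 rose and none fell over all genes, and 8 rose adjusted over the list alone, with a median of 0.41 (camera adjusted p = 1.5e-04; adjusted p = 0.277 with an estimated correlation). The chemokine gene Ccl2 rose by 2.28 (SE 0.43) and Tnfaip3, an NF-kB inhibitor, by 1.22 (SE 0.18). Of 24 proliferation genes, 8 rose and 1 fell over all genes, and 15 rose and 1 fell adjusted over the list alone. Their median was 0.87 (camera adjusted p = 3.2e-05; adjusted p = 0.277 with an estimated correlation), and 0.57 at a mean of 1 CPM. Mcm2, of the replicative helicase, rose by 1.13 (SE 0.20), and the thymidine kinase Tk1 fell by 1.15 (SE 0.16). Of 25 immediate early and heat shock genes, 4 rose over all genes and 5 adjusted over the list alone, with a median of 0.39. Camera called the list (adjusted p = 0.0382), with an adjusted p of 0.439 with an estimated correlation and 0.0597 by fry. Without IRE1fl 01, IRE1PKO 01 or IRE1PKO 02 the immediate early list was not called (camera adjusted p up to 0.131), with medians of 0.04, 0.26 and 0.26, and at a mean of 1 CPM its median was 0.16. Jun rose from 14.8 ± 1.89 to 63.5 ± 8.42 CPM and Atf3 by 2.32 (SE 0.42).

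Of 16 transcripts listed as substrates of IRE1-dependent RNA decay, 5 rose and none fell by either adjustment, with a median of 0.14 (camera adjusted p = 0.0437; adjusted p = 0.277 with an estimated correlation). Those that rose included Rtn4, Sparc, Pdgfrb and Col6a1. Sparc and Col6a1 encode matrix proteins, Pdgfrb is also in the stellate list and Rtn4 in the female-biased list. Sparc rose by 0.88 (SE 0.14) and Pdgfrb by 0.83 (SE 0.14). The Col6a1 call was lost without IRE1fl 03 or IRE1PKO 01 (edgeR adjusted p up to 0.0639), and the list call without IRE1fl 01, IRE1PKO 01 or IRE1PKO 02 (camera adjusted p up to 0.141). Of 7 adipose tissue genes, 3 rose and 1 fell over all genes, and 4 and 1 adjusted over the list alone, with a median of 0.78 (camera adjusted p = 0.0357; adjusted p = 0.39 with an estimated correlation). The 3 that rose, Pparg, Cidec and Fabp4, are also in the lipid droplet list, and Adrb3, a beta-adrenergic receptor of adipocytes, fell from 20.6 ± 0.789 to 7.89 ± 2.15 CPM. Without the filter on low counts the adipose median was 0.20. The adipose call was lost without any single IRE1PKO library (camera adjusted p up to 0.0638), and the Fabp4 call without any single library other than IRE1fl 01 (edgeR adjusted p up to 0.142).

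Camera did not call the remaining lists with all 6 libraries. Growth hormone and STAT5 signalling had 3 members lower and none higher of 16, and 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0991). The list was called without IRE1PKO 03 (median -0.41, camera adjusted p = 0.035), and its median was -0.07 without IRE1fl 03. Igfals, which encodes a partner of circulating IGF1, fell from 142 ± 8.13 to 78.0 ± 16.7 CPM. Thyroid hormone response had 4 higher and 1 lower of 20, and 4 and 2 adjusted over the list alone (camera adjusted p = 0.168). Serpina7, the thyroxine-binding globulin gene, rose from 39.6 ± 10.2 to 139.7 ± 11.4 CPM. The integrated stress response had 4 higher and 1 lower of 28 by either adjustment (camera adjusted p = 0.0788, and 0.035 without IRE1PKO 03), and Gdf15, a stress-induced hormone, rose by 1.97 (SE 0.21). Gluconeogenesis and insulin signalling had 2 higher and 3 lower of 23 by either adjustment (camera adjusted p = 0.106, fry adjusted p = 0.0441), and Pcx, pyruvate carboxylase, rose by 0.60 (SE 0.11). Glucocorticoid response had 1 higher and 2 lower of 22 by either adjustment (camera adjusted p = 0.671), and Tat fell by 1.10 (SE 0.18).

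Bile acid synthesis and transport had 4 higher and 4 lower of 29, and 6 and 11 adjusted over the list alone (camera adjusted p = 0.0975, fry adjusted p = 0.0192). Amacr, a racemase of bile acid synthesis, fell by 0.58 (SE 0.09). Xenobiotic metabolism had 7 higher and 4 lower of 30, and 11 and 5 adjusted over the list alone (camera adjusted p = 0.379). Acute phase response had 1 higher and 2 lower of 27, and 4 and 6 adjusted over the list alone (camera adjusted p = 0.72), and Itih3 fell by 0.77 (SE 0.13). Interferon-stimulated genes had 2 higher of 28 by either adjustment (camera adjusted p = 0.758). Autophagy and lysosome genes had 3 higher of 27, and 5 adjusted over the list alone (camera adjusted p = 0.0995, and 0.024 without IRE1PKO 03), and the lysosomal hexosaminidase Hexa rose by 0.75 (SE 0.10). No member of the circadian clock (22 tested, median -0.20, camera adjusted p = 0.106) or oxidative phosphorylation (34 tested, median -0.01, camera adjusted p = 0.676) passed by either adjustment. Without IRE1PKO 02 the circadian list was called (median -0.26, camera adjusted p = 0.0451), and without IRE1fl 03 its median was -0.11.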

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

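Halved counts and the sex-biased lists without the Mup, Cyp4a12, Cyp2b, Cyp3a and Sult genes were chosen after the data were seen. The other alternatives were set before. No called list and no named gene past the test changed direction under any alternative run, while the medians of 9 of the 20 uncalled lists changed sign under at least 1. The numbers of higher and lower genes stayed within 1.5 times of 849 and 577 under both other scalings, both other filters, the DESeq2 Wald test (1139 and 858), limma-voom (801 and 578), a trend without robust fitting and halved counts (867 and 597). Of the 1426 called genes, 1260 were also called with library totals only and 1412 with DESeq2 size factors. The median log2 fold change of all genes was 0.07 with library totals only. At a threshold of 0.1 there were 1299 higher and 992 lower genes, as a looser threshold must give more. Leaving out each library gave 398 to 868 higher genes, 255 to 616 lower genes and 15 to 21 lists called by camera; fewer samples were fitted each time. With an estimated correlation 0 lists were called. The RNA decay list was among those lost, though its estimated correlation of 0.0135 was near the preset 0.01. In that setting camera also uses the few residual degrees of freedom of the libraries. The adjusted p there therefore does not measure correlation between genes alone, and these parts were not told apart. Of 93 named genes past the test, 33 lost the call without at least 1 library, and 4 of the 18 called lists did: adipose tissue, immediate early genes, RNA decay substrates and T and NK cells. Of the 20 uncalled lists, 7 were called without at least 1 library: XBP1s targets, Kupffer cells and macrophages, pericentral hepatocytes, growth hormone signalling, the integrated stress response, autophagy and the circadian clock.

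The replicate numbers are shared between the genotypes, but no label says that they pair animals. The deviations of same-numbered libraries from their group means correlated at 0.07, -0.02 and 0.10, and 4 of 6 libraries correlated best with their own number, a hint from the data and not the design. With the number as a block, 1051 genes were higher and 814 lower and camera called 20 lists. Under the block the integrated stress response (adjusted p = 0.0484) and growth hormone lists (0.0484) were also called. Xbp1 passed (log2 fold change -0.50, edgeR adjusted p = 0.00414), and Cidea (0.0652), A4gnt (0.0771), Adgrf1 (0.126) and Mup19 (0.13) did not.

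Other list calls changed as follows, by camera adjusted p. Adipose tissue had 0.0615 with library totals only and 0.132 without a filter. T and NK cells had 0.0754 without a filter and 0.126 at a mean of 1 CPM, where the immediate early list had 0.119. The integrated stress response had 0.0299 without a filter and 0.0473 with halved counts, and Kupffer cells and macrophages 0.0381 without a filter. Of other named genes, Cyp1a2 did not pass with library totals only (edgeR adjusted p = 0.0535) or without a filter (0.147), nor Egr2 without robust fitting (0.0574). The cause was not tested. What depth limits was not tested, since the simulated data had the real depth. The alternative that counts duplicate libraries once was not run, because no pair was a duplicate, and those for normalized values did not apply to counts.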

Other observations

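The gene families below and Eno1b, and the tests of female livers, of reads shared within families and of growth hormone signalling, were chosen only after the results were seen. The tests of tandem families and of a segment around Ern1 were set before, but were judged to decide nothing only after their results were seen.

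Genes grouped by the stem of their symbol gave 214 families, tested with camera with Benjamini-Hochberg adjustment over the families. Camera called 14 families, 9 higher and 5 lower, and none with an estimated correlation (adjusted p of 0.813 or more). The smallest p was that of Mup, the major urinary proteins, with 4 of 19 lower and none higher (median -3.33, camera adjusted p = 2.0e-11), whose copies share reads. The other lower families, Nat, Rpl, Hist and Mrpl, had 1 or 2 members lower each. Of 13 tested Adamts genes, secreted metalloproteases of the matrix, 4 were higher in IRE1PKO and none lower (median 0.79, camera adjusted p = 0.00239). Of 11 annexin genes, 5 were higher and none lower (median 0.45, camera adjusted p = 0.00876), and of 31 collagen genes 12 were higher and none lower (median 0.38, camera adjusted p = 0.0205). The gene with the smallest p was Eno1b, which rose from 11.1 ± 1.02 to 85.7 ± 8.02 CPM (SD, n = 3). Eno1b is a near-identical copy of Eno1, so its reads are uncertain.

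The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 849 higher and 577 lower genes, and the highest of the other 9 gave 0. For each of these counts, and for the lists, 1 split of the 10 was as large, the real one. Camera called 18 lists in the real split and 6 to 16 in the others, each of which sets 2 libraries of a genotype and 1 of the other against the reverse and so keeps part of the difference between the genotypes, so these calls do not measure false calls. Fry called 16 lists in the real split and 0 in each other. In the other splits the difference between the genotypes also widens the spread within groups, which lowers the number of calls. The 0 genes and 0 fry lists there therefore do not measure false calls either.

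In IRE1PKO 13 of 29 male-biased genes were lower and 1 higher, and 6 of 22 female-biased genes higher and none lower, with an adjusted p of 0.277 for each list with an estimated correlation. Female livers are argued against, since the median Xist count of the IRE1PKO libraries was 0.00254 of their median Ddx3y count, as are shared reads as the whole source, since the male-biased list without the Mup and Cyp4a12 genes kept a median of -1.62 with 11 of 20 lower and none higher (camera adjusted p = 1.1e-11; adjusted p = 0.277 with an estimated correlation, 0.0187 by fry). The shortened male-biased list still held Serpina1e, whose reads are also uncertain among near-identical copies. It also kept members of other gene families, such as Hsd3b5 and Ces4a, so the argument against shared reads is limited. A candidate explanation for the sex-biased genes is lower growth hormone signalling in the liver, since pulses of that pituitary hormone maintain male-biased liver genes. Of the growth hormone-induced genes Igf1, Igfals, Socs2 and Cish, 2 of 4 were lower: Igf1 (-0.62, SE 0.16) and Igfals (-0.86, SE 0.14), while Socs2 (-0.05, SE 0.51) and Cish (0.43, SE 0.57) did not pass, which leaves this open. The genotype itself, and differences in body weight or liver fat between the mice, stay open and untested.

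In IRE1PKO 13 of 26 collagen and stellate cell genes, 5 of 16 recruited macrophage markers and 5 of 19 sinusoidal endothelial markers were higher. Of 20 hepatocyte genes 6 were lower. Camera with an estimated correlation called none of these lists (adjusted p of 0.277 or more), nor did fry call the endothelial list (adjusted p = 0.0963). A lower share of hepatocytes would raise the markers of all other cell types alike. The T and NK cell median had a bootstrap 95% interval with an upper bound of -0.0678, below the lower bound of 0.813 for recruited macrophages. These were the lowest and highest medians of the lists compared. The bootstrap resampled marker genes and not libraries, so it measures no spread between libraries. Only Cd4 passed among the T and NK genes, and fry did not call that list (adjusted p = 0.122). The gap between these medians argues only weakly against a lower hepatocyte share as the whole source. The bounds stayed apart without each library in turn, a check added later: without IRE1fl 01 they were 0.154 and 0.763. A change in the number of stellate cells and macrophages, or in expression within them, may underlie the rise, and bulk libraries do not separate these.

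Of the genes with coordinates, 166 were called at 4-fold or more, several of them nearly silent in 1 genotype, as a strain variant linked to the genotype could cause. The fullest 10 Mb window held 5 of them, against a 95th percentile of 8 in random draws, and 92.4% of draws had a window as full. Only a block of more than 8 such genes would have stood out. The test therefore cannot decide on a smaller block of linked variants or on scattered ones. Within 10 Mb of Ern1, 9.93% of 292 tested genes were called, against 9.75% elsewhere (one-sided exact Fisher test p = 0.487), but a segment around Ern1 carried with the floxed allele would be in IRE1fl too, so this decides nothing. Gene families in tandem moving together were tested by counting each family once, where 99.96% of random draws had a window as full; with no window fuller than chance to begin with, this test decides nothing. The genotype stays among the open explanations.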
